A study of Mus musculus with 6 samples.

How the data were processed

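Single cells from mouse melanoma tumors were measured in 6 libraries, 1 for each combination of antibody (control or anti-Ang2) and radiation (none, whole-body or focused on the tumor). Per the labels' protocols, tumors were dissociated with enzymes, red blood cells were lysed, and libraries were made with a 10x Genomics 3' kit and sequenced on a NovaSeq instrument. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization, per the file headers. Each matrix lists 31053 genes and 6794880 barcodes, so the authors' cell filter was not applied to it. Per the file headers the matrices were written by Cell Ranger 3.1.0, while the submitters' processing notes name Cell Ranger 2.1.1, genome build mm10 and Seurat 3.1.1. Gene positions came from the GENCODE M21 annotation of that build. No file with the authors' cell types was used here.

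Barcodes with at least 2000 UMIs, at least 1000 genes and mitochondrial UMIs under 15% were kept as cells. A minimum of 1000 UMIs and 500 genes had been fixed first, before the data were examined, with 2000 and 1000 as its alternative. Their roles were exchanged before any groups were compared, because the peak of empty droplets lay at 422 to 1188 UMIs. Doublets were scored in each library by comparison with simulated doublets, and the highest-scoring 0.8% per 1000 called cells, 4.49% to 7.66% of a library, were removed. Cells of all libraries were clustered together, without integration, in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, leidenalg 0.10.2). Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbors and a Leiden resolution of 1 were used. A cluster took the name of the class with the highest mean log2 marker score, if that was at least 1.0, led the next class by 0.3 and rested on at least 3 detected markers. Clusters led by genes of another class, or with few UMIs and no marker among their leading genes, stayed unnamed. The markers of 17 classes and 26 gene lists were fixed before the data were examined.

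UMIs were summed over the cells of a class in each library, since cells are not replicates. Class sums ranged from 60296278 to 171681320 UMIs in malignant-like cells, 1240317 to 8314200 in macrophage/monocyte-like cells, 901132 to 3644009 in endothelial-like cells and 297164 to 3187807 in T/NK-like cells, which joined T cell-like and NK cell-like clusters. These 4 classes had at least 20 cells in every library and were tested. Fibroblast-like and pericyte-like cells also had at least 20 in every library but were not tested. In edgeR 4.0.16 (R 4.3.3), genes were filtered with filterByExpr, scaled with TMM and fitted with antibody and kind of radiation as additive terms, without robust dispersion. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test. The model left 2 residual degrees of freedom, and 1 with a library left out, where the missing condition is assumed to follow the additive model and to vary like the others. A single condition and the interaction could not be tested, since no degrees of freedom remain. Ratios between single libraries, with 0.5 added to each count, are given as values only.

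Genes were named by a rule fixed before the data were examined. It took up to 10 called genes per direction with the largest fitted change, a mean of at least 20 CPM and the same direction in every pair, 3 members of each described list, and a fixed set that included Angpt1, Angpt2, Tek, Cdkn1a, Mki67, Isg15, Cd274 and H2-K1. Where fewer than 5 genes qualified, those with the largest smallest-pair ratio were taken instead, past no test. Some genes that the rule takes are left out of the text. Genes outside the rule are said to have been chosen after their values were seen. Counts for a list are given over all genes tested and adjusted over the list alone. Shares of cells have exact 95% binomial intervals, and their pair differences an exact two-sided sign-flip permutation test.

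Free RNA was measured with 2 profiles. The planned one, from barcodes with 10 to 50 UMIs, held RNA that the pericyte-like class lacked. Tek was at 44.5 to 91.7 CPM in that profile, and had 0 UMIs in the pericyte-like class of every library. A profile of empty droplets with 500 to 1000 UMIs, where Tek was at 0.780 to 1.20 CPM, was therefore added after seeing the data and used for the percentages of free RNA. With markers of a class taken as absent from another, it put the upper limit of free RNA at 21.0% to 42.3% of UMIs in malignant-like cells, 14.5% to 23.7% in macrophage/monocyte-like cells, 7.55% to 14.7% in endothelial-like cells and 17.1% to 37.1% in T/NK-like cells. These limits, and those given below for single genes, hold for this profile only. With the 10 to 50 UMI profile they reached 45.4% in macrophage/monocyte-like, 24.9% in endothelial-like and 71.1% in T/NK-like cells, but 12.0% in malignant-like cells. The 500 to 1000 window also missed the peak of empty droplets in the non-irradiated control (422 UMIs) and whole-body anti-Ang2 (1188.5 UMIs) libraries. The reported counts were not corrected for free RNA.

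The test was tried on counts simulated from the means and library sizes of these libraries, with 200 genes changed. The simulated libraries held no radiation effect, no interaction and no spread of dispersion between genes beyond its trend with expression. Recovery in the real data can therefore be lower. For the antibody effect, 2-fold changes were recovered for 86% of changed genes in malignant-like cells (15792 genes), 80% in macrophage/monocyte-like cells (10926 genes), 72% in endothelial-like cells (9589 genes) and 64% in T/NK-like cells (7698 genes). Changes of 1.5-fold were recovered for 70%, 30%, 34% and 16%, in the same order. Alternatives covered the UMI and gene minimum, the mitochondrial limit, doublets, the clustering resolution, the scaling (DESeq2 1.42.0 size factors), DESeq2's Wald test, the low-count filter, free-RNA subtraction, the radiation terms, the libraries fitted, the denominator of the shares and leaving out each library. Size factors of DESeq2 moved the median log2 change by at most 0.0118.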

Results

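Mouse melanoma tumor samples, 6 in all, from C57BL/6 mice aged 20 weeks were profiled by single-cell RNA sequencing, in a design that crossed 2 antibodies with 3 kinds of radiation. Mice received a control antibody or an antibody that blocks angiopoietin-2 (Ang2, the product of Angpt2, a vascular growth factor that binds the endothelial receptor Tie2, encoded by Tek). Each antibody was combined with no radiation, whole-body radiation or radiation focused on the tumor. The title of the series names the question as what anti-Ang2 and radiation change in the single cells of melanoma tumors. Every condition had 1 library, so no condition had a replicate. The libraries are called below the non-irradiated, whole-body and focused control libraries and the non-irradiated, whole-body and focused anti-Ang2 libraries. The labels do not say whether a library came from 1 tumor or a pool, and they call the non-irradiated control both antibody-treated and untreated.

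Total UMI counts were 253870708, 258531071 and 264615654 in the non-irradiated, whole-body and focused control libraries, and 229193335, 236239557 and 153262904 in the matching anti-Ang2 libraries. The design text gives 10000 cells per sample, and each deposited matrix lists 6794880 barcodes. After filtering, 8364, 6785 and 8846 cells remained in the control libraries and 7945, 7459 and 5356 in the anti-Ang2 libraries. The median cell held 22529.5, 26291 and 22070 UMIs in the control libraries and 10732, 16192 and 8533 in the anti-Ang2 libraries. Clusters were named from fixed markers as malignant-, macrophage/monocyte-, T cell-, NK cell-, dendritic-, endothelial-, pericyte/smooth muscle-, fibroblast-, B cell- or keratinocyte-like. Clusters left without a name held 9.62%, 15.5% and 10.3% of cells in the control libraries and 9.19%, 24.2% and 9.67% in the anti-Ang2 libraries, in the same order. Of these, clusters 3, 12, 16 and 25 scored highest for the malignant-like class and cluster 23 for the macrophage/monocyte-like class. The malignant-like shares below leave them out, which weighs most on the whole-body anti-Ang2 library.

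Malignant-like cells made up a smaller share of every anti-Ang2 library than of the control library with the same radiation. They were 66.3% of cells without radiation in the control library (exact 95% binomial interval 65.3 to 67.3) and 44.1% with anti-Ang2 (43.0 to 45.2). The shares were 75.0% and 55.9% after whole-body radiation, and 70.7% and 32.7% after focused radiation. The mean difference was -26.4 percentage points ± 10.1 (SD, n = 3 pairs). Immune-like cells were higher with anti-Ang2 in all 3 pairs, by 14.6 points ± 11.1 (SD), from 17.0% to 32.7% without radiation, 5.11% to 8.12% after whole-body radiation and 12.0% to 37.1% after focused radiation. Within them, macrophage/monocyte-like cells differed by 8.20 points ± 6.21 (SD) and T cell-like cells by 4.98 points ± 3.52 (SD). Endothelial-like cells differed by 1.81 points ± 2.01 (SD), fibroblast-like cells by 4.40 points ± 1.55 (SD) and pericyte-like cells by 3.04 points ± 1.21 (SD). Each of these differences had the same direction in all 3 pairs, and an exact two-sided sign-flip permutation test of 3 pairs gave p = 0.25, the smallest it allows. The intervals cover counting error only.

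**Figure D1:**
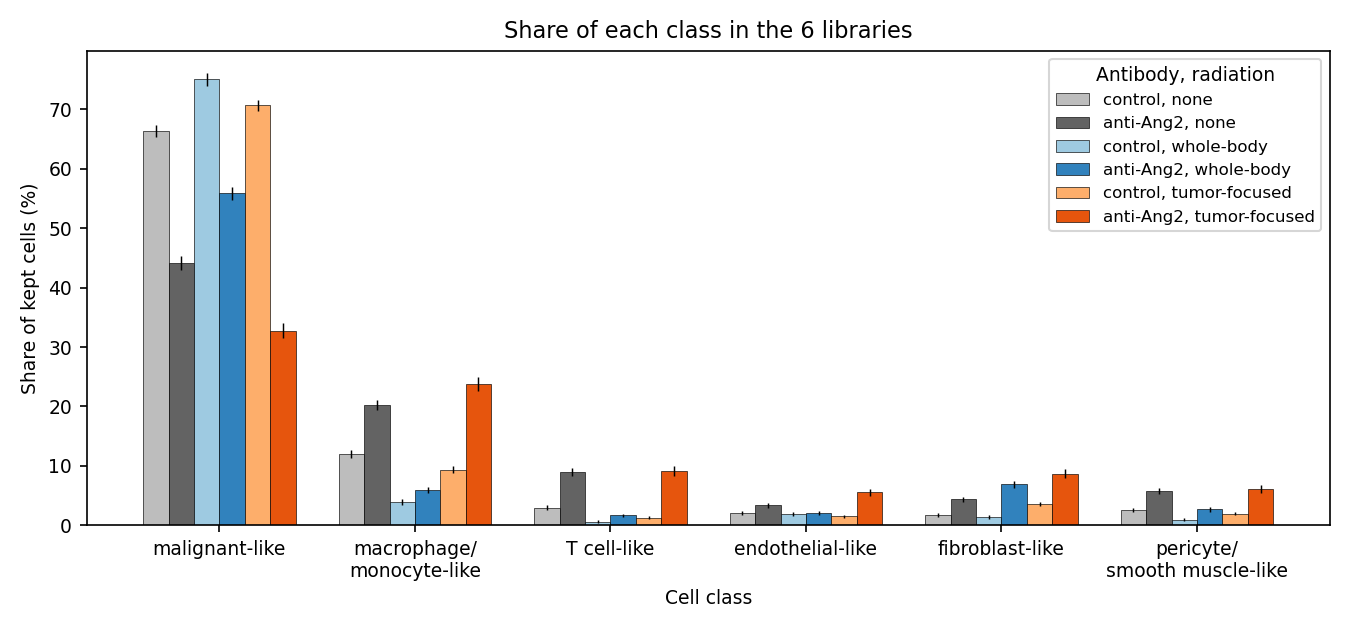
Share of kept cells (%) in 6 cell classes, 1 bar per library, with exact 95% binomial intervals for counting error only. Bars are ordered by radiation, with the control antibody before anti-Ang2 in each pair; the malignant-like share falls from 66.3% to 44.1%, from 75.0% to 55.9% and from 70.7% to 32.7% within the 3 pairs.

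These shares rest on the cells that passed the UMI minimum and on the denominator. With at least 1000 UMIs and 500 genes, where empty droplets also pass, the antibody difference in malignant-like cells was -9.84 points. Among non-malignant cells the endothelial-like difference was -0.0477 points and the macrophage/monocyte-like difference 0.552 points. With clusters without a name left out of that denominator as well, the antibody difference for T cell-like cells was 6.05. It was -3.30 points for endothelial-like, -8.77 for macrophage/monocyte-like and -4.12 for immune-like cells, the reverse of their direction among all cells. Fibroblast-like cells were then 318 of 1687 in the focused control library and 463 of 3084 with anti-Ang2, a lower share. Their non-irradiated and whole-body pairs stayed higher with anti-Ang2. Pericyte-like cells stayed higher in each pair, but were nearly equal in the focused one, at 175 and 329 of these totals.

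Whole-body radiation went with fewer immune-like cells with either antibody. Macrophage/monocyte-like cells were 12.0% and 3.94% of the non-irradiated and whole-body control libraries, and 20.2% and 5.91% of the matching anti-Ang2 libraries, a mean difference of -11.2 points ± 4.41 (SD, n = 2 pairs). T cell-like cells were 2.95% and 0.604% with the control antibody and 8.95% and 1.66% with anti-Ang2, a mean difference of -4.82 points ± 3.49 (SD). Dendritic-like cells differed by -1.43 points ± 0.207 (SD) and malignant-like cells by 10.2 points ± 2.13 (SD). Focused radiation showed no such common direction. Macrophage/monocyte-like cells were 9.35% in the focused control library, a difference of -2.65 points from the non-irradiated one, and 23.7% in the focused anti-Ang2 library, 3.54 points above its counterpart. T cell-like cells were 1.25% and 9.13% in these libraries. Fibroblast-like cells were higher after focused radiation with both antibodies, by 3.06 points ± 1.72 (SD). An exact sign-flip permutation test of 2 pairs cannot give a p under 0.5.

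Gene expression was compared on UMI counts summed over the cells of a class in each library. An additive model of antibody and radiation was fitted with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. Values in parentheses after a gene are fitted log2 changes ± standard error over the 6 libraries. Counts are of genes with an adjusted p under 0.05, and genes named as risen or fallen also had the same direction in all 3 antibody pairs or both radiation pairs. The class sums do not separate a change within cells from a change in the mix of clusters. UMIs given for single genes are raw and were not scaled to these sums, which differ between libraries. With 2 residual degrees of freedom, the error holds both the interaction and the spread between libraries, and the p-values cannot tell treatment from differences between single tumors. Near-identical family members can share reads, so the values of Gzmc and Gzmf, Ifit3 and Ifit3b, Lyz1, Mcpt2, the histone genes and the H2 class I genes are uncertain as to the member.

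In endothelial-like cells, interferon, antigen presentation, sprouting, and immediate-early and dissociation genes were higher with anti-Ang2, and G2/M genes were lower. Angpt2 itself (ENSMUSG00000031465, mm10 chromosome 8, 18690263 to 18741562, minus strand) rose (1.00 ± 0.13, adjusted p = 0.00011). It stood at 503, 578 and 706 CPM in the non-irradiated, whole-body and focused control libraries and at 868, 1332 and 1421 CPM in the matching anti-Ang2 libraries. Its receptor Tek (ENSMUSG00000006386, chromosome 4, 94739289 to 94874976, plus strand) fell (-0.49 ± 0.14, adjusted p = 0.049), while the related receptor Tie1 (-0.11 ± 0.13) and the VEGF receptor gene Kdr (0.00 ± 0.13) did not pass. In total 286 genes rose and 152 fell among 9790 tested, and 1592 had an unadjusted p under 0.05.

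The G2/M list, genes of late cell division, fell most broadly in this comparison, with 20 of 28 members lower and none higher, and 26 lower when adjusted over the list alone. Of the G1/S list 2 of 27 were lower (3 adjusted over the list alone). The mitotic cyclin genes Ccna2 (-1.37 ± 0.23) and Ccnb1 (-1.13 ± 0.25), the mitotic ubiquitin-conjugating enzyme gene Ube2c (-1.30 ± 0.17) and the proliferation marker Mki67 (-0.71 ± 0.16) were among them. Free RNA could make up at most 29%, 41%, 25% and 16% of the endothelial UMIs of Ccna2, Ccnb1, Ube2c and Mki67. Among tested genes with a mean of at least 20 CPM, the largest fall was that of Ptn (ENSMUSG00000029838, chromosome 6, 36714929 to 36810220, minus strand), which encodes the secreted growth factor pleiotrophin, with 687, 100 and 300 UMIs in the control libraries and 68, 0 and 15 with anti-Ang2. Further falls were seen in Robo1, a guidance receptor gene (-1.94 ± 0.31), Tfpi2, a protease inhibitor gene (-1.78 ± 0.23), Prcp, which encodes a prolylcarboxypeptidase (-1.69 ± 0.16), Adamts5, a matrix protease gene (-1.49 ± 0.16), and Itga2, an integrin gene (-1.48 ± 0.14). Adgrg3 (-1.36 ± 0.28), Igfbp4, for an insulin-like growth factor binding protein (-1.30 ± 0.13), and Sele, for the adhesion molecule E-selectin (-1.28 ± 0.20), fell as well. Phlda3, a p53 target, fell (-0.59 ± 0.12), and the p53 targets Cdkn1a (0.42 ± 0.13), Mdm2 (0.05 ± 0.16) and Ccng1 (-0.10 ± 0.15) did not pass. Of the p53 list as a whole 4 of 28 members rose and 1 fell (5 and 4 adjusted over the list alone).

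**Figure D2:**
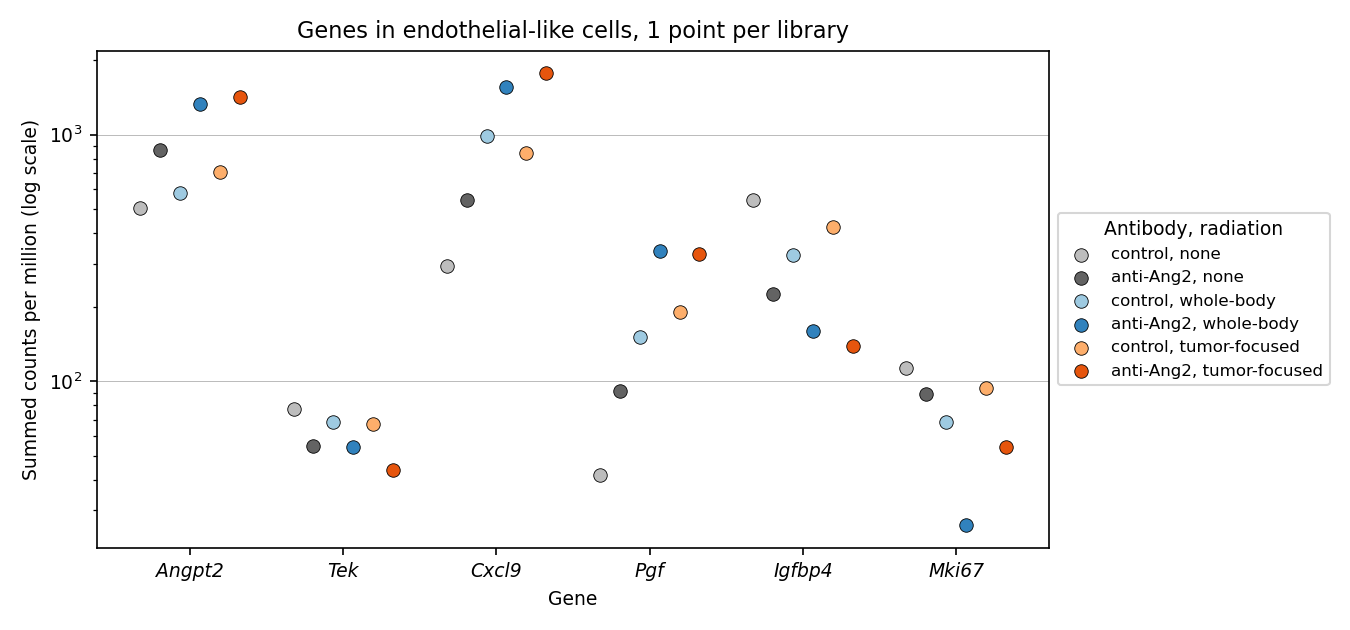
Summed CPM (log axis) of 6 genes in endothelial-like cells, 1 point per library, colored by antibody and radiation and ordered as control then anti-Ang2 within each kind of radiation. Angpt2 lies at 503, 578 and 706 CPM with the control antibody and at 868, 1332 and 1421 CPM with anti-Ang2, while Tek, Igfbp4 and Mki67 are lower with anti-Ang2 in each pair.

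Of the interferon list, 12 of 36 members rose with anti-Ang2 in endothelial-like cells and none fell (20 and 0 adjusted over the list alone), and 6 of 18 MHC class I members rose (13 and 0 adjusted over the list alone). Examples were Irf1, an interferon-regulated transcription factor gene (1.01 ± 0.18), the guanylate-binding protein gene Gbp2 (0.97 ± 0.14), the T cell-attracting chemokine gene Cxcl9 (0.87 ± 0.13), H2-T23 (0.86 ± 0.14), H2-Q4 (0.71 ± 0.13) and H2-K1 (0.49 ± 0.14). Isg15 (0.30 ± 0.14) did not pass. Cd274, which encodes the checkpoint ligand PD-L1, rose (1.40 ± 0.19). Of the immediate-early and dissociation list, 11 of 21 rose, among them Fosb (1.16 ± 0.15), Socs3, a feedback inhibitor of cytokine signaling (1.41 ± 0.15), and Zfp36 (1.15 ± 0.15), with 13 higher and 1 lower when adjusted over the list alone. The sprouting list had 5 members up and 1 down of 22 (8 and 2 adjusted over the list alone), including Pgf, for placental growth factor (1.00 ± 0.13). The adhesion list had 5 up and 1 down of 13 (7 and 2 adjusted over the list alone), with Il6 (1.44 ± 0.20) and Cxcl1 (1.03 ± 0.15) up. Large rises were also seen in Itih5, a hyaluronan-associated protein gene (2.05 ± 0.15), Clic5 (1.54 ± 0.17), Bcam (1.48 ± 0.19), Serpine2 (1.44 ± 0.24), Fam129a (1.64 ± 0.24) and the neutrophil chemokine gene Cxcl2 (1.83 ± 0.26). Rgs5 (2.08 ± 0.33) and Meg3 (2.60 ± 0.31), which lead the pericyte-like cluster, rose in the endothelial-like class too. Rgs5 had 36, 18 and 53 UMIs in the control libraries and 339, 393 and 207 with anti-Ang2. In the focused pair the class held 1149520 and 3644009 UMIs, so most of that pair's gap in Rgs5 UMIs follows the class sums. The matrix list had 5 of 21 up and 1 down (10 and 2 adjusted over the list alone), and the inflammatory macrophage list 6 of 10 up (7 and 1 adjusted over the list alone).

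The endothelial antibody count rested on the non-irradiated libraries: without the control one 4 genes passed and without the anti-Ang2 one 22, while 664 passed without the whole-body control. Of the 37 genes named as risen or fallen, 3 stayed past the threshold without each library in turn, and 37 kept their direction. DESeq2's Wald test gave 135 genes, and the count was 56 with at least 1000 UMIs and 500 genes per cell and 679 without the low-count filter. Without radiation terms the count was 19. It was 195 with the profile of barcodes with 10 to 50 UMIs subtracted and 353 with the empty-droplet profile subtracted.

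In the macrophage/monocyte-like class as a whole, genes of perivascular and alternatively activated macrophages were higher with anti-Ang2. Of the corresponding list 5 of 23 members rose and none fell (11 and 1 adjusted over the list alone). These included the eosinophil and T cell chemokine gene Ccl8 (1.14 ± 0.16), the resistin-like gene Retnla (1.27 ± 0.22), the hyaluronan receptor gene Lyve1 (1.44 ± 0.23) and Vegfa, for the main vascular growth factor (0.80 ± 0.12). In total 53 genes rose and 4 fell of 11108 tested. Saa3, an acute-phase gene (2.20 ± 0.26), Inhba, for the activin A subunit (1.20 ± 0.14), the arginine transporter gene Slc7a2 (1.00 ± 0.18), the cystine transporter gene Slc7a11 (0.90 ± 0.13), Mmp19 (1.03 ± 0.16), Slc28a2 (1.04 ± 0.15), Crem (1.05 ± 0.20), Lyz1 (1.00 ± 0.19), Klf4 (0.92 ± 0.12), Nr4a2 (0.86 ± 0.12) and the p53 inhibitor gene Mdm2 (0.63 ± 0.13) rose. The thymidine kinase gene Tk1 (-0.88 ± 0.15) and the histone chaperone gene Asf1b (-0.86 ± 0.16) fell, and 18 of 28 G2/M members were lower when adjusted over the list alone, although none passed over all genes. Mki67 (-0.55 ± 0.13), Cd274 (0.50 ± 0.12), Cdkn1a (0.32 ± 0.13), H2-K1 (0.33 ± 0.13) and Isg15 (0.19 ± 0.25) did not pass. Mcpt2, a mast cell protease gene, passed with fewer UMIs in the non-irradiated and focused pairs, 1117 and 411 against 272 and 0, but had 0 UMIs in both whole-body libraries and so no direction in that pair. The platelet chemokine gene Ppbp (-2.99 ± 0.52), chosen after its values were seen, fell at 7, 17 and 55 UMIs in the control libraries against 5, 0 and 12.

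Cluster 5, led by C1qa, C1qb and C1qc, held most macrophage/monocyte-like cells in every library except the focused anti-Ang2 one, where cluster 9, led by Il1b, Cxcl2 and H2-Ab1, did. Cluster 21, whose leading genes include Ccl8, Mrc1, Cd209f and Folr2, held 34, 12 and 28 of the 1004, 267 and 827 cells of the class in the control libraries and 66, 119 and 65 of 1606, 441 and 1272 with anti-Ang2. Saa3 is a leading gene of a fibroblast-like cluster, and of the matrix list 24 of 25 members were higher with anti-Ang2 in the macrophage/monocyte-like class, 2 past the threshold and 12 adjusted over the list alone. The macrophage count was 107 without the non-irradiated anti-Ang2 library, 762 without the whole-body control, 804 without the whole-body anti-Ang2, 31 without the focused control and 114 without the focused anti-Ang2 library. It was 0 without radiation terms, 1 with at least 1000 UMIs and 500 genes, 178 with at least 3000 and 1500, and 379 without the low-count filter. Subtracting the 10 to 50 UMI profile left 0 and the empty-droplet profile 20. Of the 19 named genes past the threshold, 7 stayed past it without each library in turn.

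In T/NK-like cells, 37 genes were higher and 15 lower with anti-Ang2 of 7961 tested. Tnfaip3, a feedback inhibitor of NF-kB signaling (0.99 ± 0.17), the chemokine receptor gene Cxcr4 (0.94 ± 0.18), the growth factor gene Areg (0.84 ± 0.18), Vps37b (1.21 ± 0.17), the histone demethylase gene Kdm6b (0.99 ± 0.18), Ier5l (1.10 ± 0.21), Nmrk1 (1.20 ± 0.28) and Dgat1, for a triglyceride synthesis enzyme (1.10 ± 0.22), rose. The chemokine gene Xcl1 (-0.81 ± 0.14), the NK receptor gene Klra1 (-1.26 ± 0.24), the heat-shock gene Hspa1a (-1.08 ± 0.22), the replication gene Pclaf (-0.92 ± 0.19) and the kinetochore gene Spc25 (-1.10 ± 0.24) fell. The granzyme genes moved apart, Gzmf up (2.21 ± 0.34) and Gzmc down (-1.94 ± 0.34). Gzmf had 0, 1 and 21 UMIs in the control libraries against 32, 6 and 436. The class held 579276 and 2751140 UMIs in the focused pair. Xcl1 and Gzmc lead the NK cell-like cluster, which held 46, 27 and 31 cells beside 247, 41 and 111 T cell-like ones in the control libraries and 116, 27 and 81 beside 711, 124 and 489 with anti-Ang2, a smaller part in each pair. Of the matrix list 10 of 11 members were higher in this class (1 past the threshold, 7 adjusted over the list alone), and of the pigmentation list 13 of 16 (0 in either count). By markers of malignant-like cells, free RNA was at most 18.3%, 19.3% and 19.1% of the class in the control libraries and 25.1%, 37.1% and 17.1% with anti-Ang2. Of the effector list 1 of 18 members rose and 2 fell (2 and 2 adjusted over the list alone), and 13 of 27 G1/S genes were lower when adjusted over the list alone, with 0 past the threshold over all genes. Mki67 (-0.40 ± 0.17), Cdkn1a (0.41 ± 0.17), Isg15 (0.42 ± 0.18) and H2-K1 (0.08 ± 0.13) did not pass. The count was 206 without the whole-body anti-Ang2 library, 212 without the whole-body control and 24 without the non-irradiated control. It was 3 without radiation terms, 18 with at least 1000 UMIs and 500 genes, 25 by DESeq2's Wald test, 141 without the low-count filter, 260 with at least 3000 UMIs and 1500 genes and 448 at 2000 UMIs after scaling to the shallowest library. With the 10 to 50 UMI profile subtracted it was 0, and with the empty-droplet profile 36. Of 15 genes named as risen or fallen, 4 stayed past the threshold without each library in turn.

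In malignant-like cells no gene passed for the antibody by edgeR's quasi-likelihood test, out of 16007 tested, although 3319 had an unadjusted p under 0.05. DESeq2's Wald test called 301 up and 384 down. When adjusted over the list alone, 14 of 18 MHC class I genes and 19 of 36 interferon genes were higher and none lower. Values were 0.74 ± 0.17 for H2-K1, 0.82 ± 0.16 for H2-T23, 0.76 ± 0.17 and 0.81 ± 0.18 for the peptide transporter genes Tap1 and Tap2, 1.10 ± 0.23 for Gbp2, 1.07 ± 0.29 for Iigp1 and 1.01 ± 0.17 for Irf1, with adjusted p between 0.11 and 0.15. Hes1, a Notch target (0.75 ± 0.12), Skil (0.47 ± 0.05) and the receptor kinase gene Axl (0.71 ± 0.14) were higher in all 3 pairs, and Fabp3 (-0.58 ± 0.06), Rfc5 (-0.41 ± 0.05) and Dtymk (-0.36 ± 0.06) lower. Macrophage genes moved with them: 15 of 20 inflammatory macrophage genes and 8 of 11 MHC class II genes were higher in the malignant-like class when adjusted over the list alone. Mki67 (0.01 ± 0.07), Cdkn1a (-0.08 ± 0.09), Vegfa (0.25 ± 0.09), Cd274 (0.78 ± 0.19), Isg15 (0.21 ± 0.26), Angpt2 (-0.11 ± 0.07) and Angpt1 (0.42 ± 0.35) did not pass. Cluster 0, led by Trpm1, was the largest malignant-like cluster in the non-irradiated libraries, cluster 2, led by Ptgds, in both whole-body libraries and the focused anti-Ang2 one, and cluster 4, led by Bnip3, in the focused control. The count was 1105 without the whole-body control, 1294 without the whole-body anti-Ang2, 72 without the focused control and 32 without the focused anti-Ang2 library. It was 364 with at least 1000 UMIs and 500 genes.

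**Figure D3:**
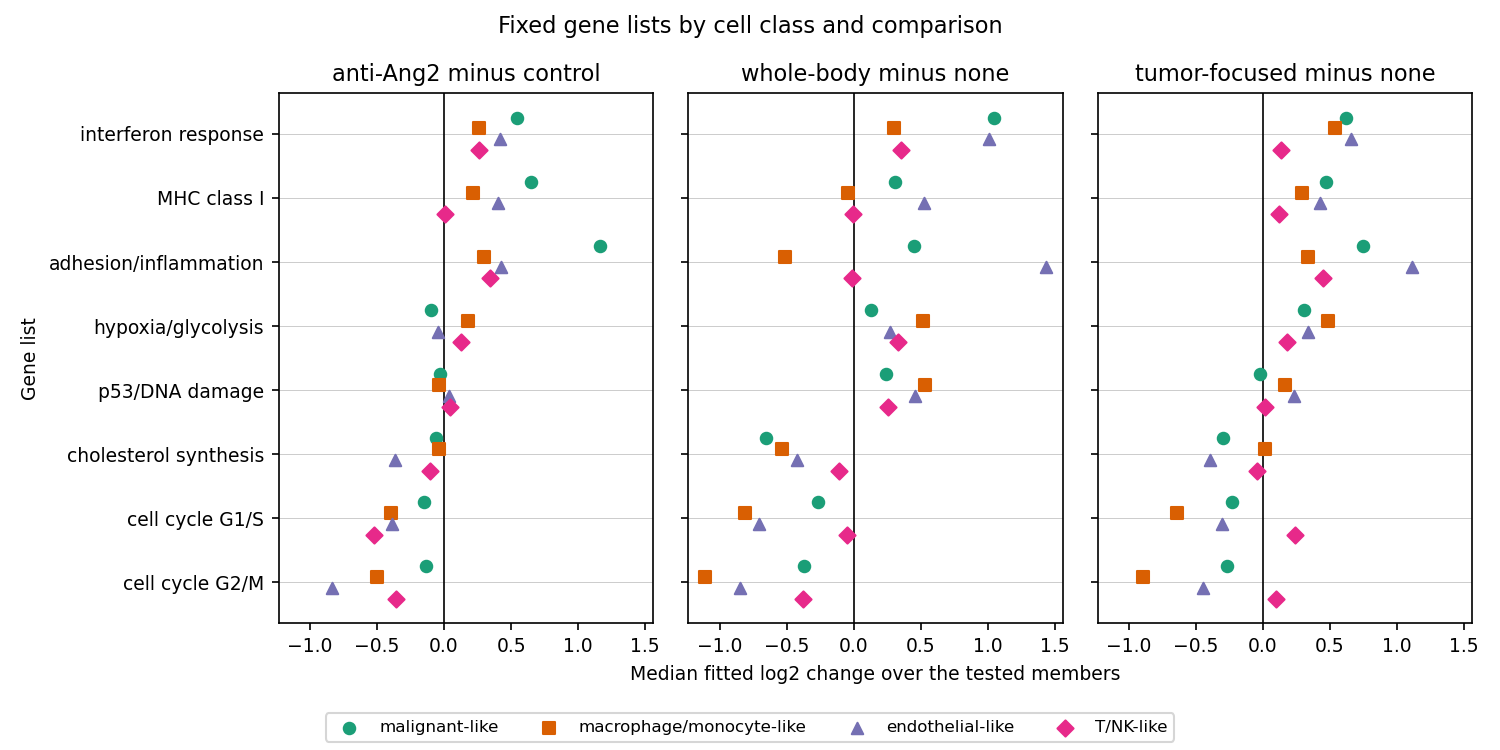
Median fitted log2 change over the tested members of 8 fixed gene lists (x axis) in 4 cell classes, in 1 panel each for anti-Ang2 minus control, whole-body minus none and tumor-focused minus none. The G2/M median is -0.84 in endothelial-like cells with anti-Ang2 and -1.11 in macrophage/monocyte-like cells after whole-body radiation, and the interferon median is 1.05 and 1.01 in malignant-like and endothelial-like cells after whole-body radiation.

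Interferon, adhesion and p53 target genes were higher in endothelial-like cells after whole-body radiation. Of the interferon list 27 of 36 members rose and none fell (32 and 0 adjusted over the list alone), with a median of 1.01, led by the antiviral genes Rsad2 (2.27 ± 0.18), Ifit3 (2.02 ± 0.17) and Ifit3b (1.91 ± 0.18), the chemokine gene Cxcl10 (2.00 ± 0.17) and Isg15 (1.09 ± 0.17). Of the adhesion list 10 of 13 members rose (11 and 0 adjusted over the list alone), among them Selp, for P-selectin (2.20 ± 0.19), and Vcam1, which binds leukocyte integrins (1.66 ± 0.22). Of the p53 list 6 of 28 rose (9 and 0 adjusted over the list alone), with the cell-cycle inhibitor gene Cdkn1a (1.58 ± 0.16), Ccng1 (1.03 ± 0.19) and Phlda3 (0.97 ± 0.15), while Mdm2 (0.41 ± 0.20) did not pass. The signaling genes Bmp2 (2.64 ± 0.29), Tnfrsf9 (1.96 ± 0.26), Pgf (1.86 ± 0.17) and Cd274 (1.88 ± 0.24) rose. Ubd (2.14 ± 0.23), the matrix gene Fn1 (1.57 ± 0.28), the oxygen-sensing gene Egln3 (1.62 ± 0.37), H2-K1 (0.71 ± 0.17) and H2-T23 (0.78 ± 0.18) rose too. The G2/M list had 9 of 28 members down and none up (23 down adjusted over the list alone), including Mki67 (-1.22 ± 0.21), Kif23 (-1.40 ± 0.31), and outside the list Kif20b (-1.65 ± 0.31), Pclaf (-1.35 ± 0.25) and the linker histone gene Hist1h1b (-2.81 ± 0.38). The imprinted gene Mest (-1.66 ± 0.16), Ptn (-2.20 ± 0.32) and the potassium channel subunit gene Kcne3 (-1.01 ± 0.15) fell. Of the matrix list 9 of 21 members rose (14 and 0 adjusted over the list alone; median 0.94), and of the inflammatory macrophage list 5 of 10 (5 and 0 adjusted over the list alone). Angpt2 (0.42 ± 0.16), Tek (-0.09 ± 0.17), Tie1 (-0.10 ± 0.16) and Kdr (0.28 ± 0.16) did not pass.

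In all, 254 endothelial genes rose and 98 fell with whole-body radiation. The count was 0 without the non-irradiated control, 2 without the non-irradiated anti-Ang2, 577 without the focused control and 581 without the focused anti-Ang2 library, and none of the 27 genes named as risen or fallen stayed past the threshold without each library in turn, although 27 kept their direction. It was 112 by DESeq2's Wald test, 14 with at least 1000 UMIs and 500 genes and 532 without the low-count filter, and 254 and 281 with the 10 to 50 UMI and empty-droplet profiles subtracted.

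In macrophage/monocyte-like cells, cell division and inflammatory cytokine genes were lower after whole-body radiation, and alternative activation, hypoxia and p53 target genes were higher. Of the G2/M list 22 of 28 members fell (27 adjusted over the list alone) and of the G1/S list 13 of 27 (20 adjusted over the list alone), and none of either rose. Examples were Mki67 (-1.54 ± 0.17), Ube2c (-1.47 ± 0.19), Tk1 (-1.72 ± 0.21), the replication helicase gene Mcm5 (-1.32 ± 0.27) and Hist1h1b (-1.73 ± 0.28). The inflammatory list had 7 of 21 down and 3 up (13 and 3 adjusted over the list alone), with the cytokine genes Il1b (-1.38 ± 0.16), Tnf (-1.11 ± 0.17) and Ccl4 (-1.20 ± 0.15) down and the nitric oxide synthase gene Nos2 (2.08 ± 0.29) up. The MHC class II list had 4 of 12 down (4 down and 1 up adjusted over the list alone), with H2-Eb1 (-1.38 ± 0.20) and H2-Aa (-1.29 ± 0.20). The cholesterol synthesis list had 6 of 18 down (12 adjusted over the list alone), including Cyp51 (-1.24 ± 0.20). Of the alternative activation list 11 of 23 rose (12 up and 1 down adjusted over the list alone), with Arg1, for arginase 1 (2.41 ± 0.16), and the lectin gene Cd209f (2.61 ± 0.30). Of the p53 list 13 of 28 rose (13 adjusted over the list alone), including Cdkn1a (1.07 ± 0.16), Ccng1 (1.13 ± 0.15), Phlda3 (1.31 ± 0.17) and Mdm2 (0.58 ± 0.16), and of the hypoxia list 13 of 32 (21 adjusted over the list alone). At most 77% of the Phlda3 UMIs in this class could be free RNA. Of the melanocyte pigmentation list 15 of 20 members were higher in this class too, 4 past the threshold and 5 adjusted over the list alone. By markers of malignant-like cells, free RNA was at most 20.6% and 23.7% of the class in the whole-body control and anti-Ang2 libraries, against 17.6% and 17.3% in the non-irradiated ones.

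Large rises in macrophage/monocyte-like cells after whole-body radiation were those of the chemokine gene Ccl17 (5.25 ± 0.46), with 4 and 75 UMIs in the non-irradiated control and anti-Ang2 libraries against 354 and 368, and of the metalloproteinase genes Mmp12 (3.05 ± 0.29) and Mmp13 (2.32 ± 0.21). Slc7a2 (2.59 ± 0.24), Fcna (2.52 ± 0.37), Inhba (2.15 ± 0.19), Areg (1.82 ± 0.22) and Cd274 (0.68 ± 0.15) rose too. Mast cell protease genes in this class were at or near 0 after whole-body radiation: Mcpt2 had 1117 and 272 UMIs in the non-irradiated libraries and 0 in both whole-body ones, and Cma1 had 280 and 172 against 0 and 2. Ly6i (-3.20 ± 0.50), the chemokine gene Cxcl14 (-2.50 ± 0.26) and Spon1 (-1.74 ± 0.27) fell. Isg15 (0.15 ± 0.30), Vegfa (0.31 ± 0.15) and H2-K1 (0.32 ± 0.15) did not pass. In total 378 genes rose and 302 fell. The count was 340 without the non-irradiated control, 271 without the non-irradiated anti-Ang2, 1529 without the whole-body control and 1070 without the focused anti-Ang2 library, and 27 of 30 genes named as risen or fallen stayed past the threshold without each library in turn. Without the whole-body control, Isg15 was at -0.70. DESeq2's Wald test gave 280 and the 1000-UMI minimum 236. With the 10 to 50 UMI profile subtracted none of the 680 genes passed, and with the empty-droplet profile 549 genes did. Cluster 21, of which Cd209f is a leading gene, held 34 of 1004 and 66 of 1606 cells of the class in the non-irradiated control and anti-Ang2 libraries and 12 of 267 and 119 of 441 in the whole-body ones.

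In the T/NK-like class as a whole, regulatory T cell genes were lower and effector genes higher after whole-body radiation, as the mix of its clusters shifted. Cluster 17, led by Ctla4, Tnfrsf4, Icos and Ikzf2, held 109 and 344 of the 247 and 711 T cell-like cells in the non-irradiated control and anti-Ang2 libraries, and 7 and 23 of 41 and 124 in the whole-body ones. NK cell-like cells numbered 46 and 116 in the former and 27 and 27 in the latter. Of the regulatory list 6 of 11 members fell and none rose (9 and 0 adjusted over the list alone), among them the checkpoint receptor gene Ctla4 (-1.89 ± 0.21) and Areg (-1.76 ± 0.24). The lineage factor gene Foxp3 (-1.33 ± 0.27), Ikzf2 (-1.33 ± 0.18) and Tnfrsf4 (-1.35 ± 0.20), which were chosen after their values were seen, fell as well. Klrg1 (-1.77 ± 0.50) did not pass. Izumo1r, for folate receptor 4 (-2.79 ± 0.32), the integrin gene Itgb8 (-1.62 ± 0.32) and Dapl1 (-3.44 ± 0.69; 36 and 70 UMIs against 2 and 0) also fell. Of the effector list 5 of 18 rose (7 and 0 adjusted over the list alone), including interferon gamma, Ifng (2.07 ± 0.20), the perforin gene Prf1 (1.61 ± 0.32), Gzmc (2.33 ± 0.42) and, chosen after its values were seen, Gzmb (0.94 ± 0.22). Cdkn1a (1.94 ± 0.20) and Ccdc184 (1.69 ± 0.38) rose, and Mki67 (-0.74 ± 0.22), Isg15 (0.44 ± 0.22) and H2-K1 (-0.06 ± 0.15) did not pass. Pigmentation genes of the melanocyte list moved with radiation in this class: 9 of 16 were higher when adjusted over the list alone, and at most 32% of its Cdkn1a UMIs could be free RNA. Altogether 41 genes rose and 24 fell. The count was 14 without the non-irradiated control, 36 without the non-irradiated anti-Ang2, 221 without the whole-body control, 165 without the focused control and 172 without the focused anti-Ang2 library. The Wald test of DESeq2 gave 21 genes, and leaving out the low-count filter 148. With the 10 to 50 UMI profile subtracted 0 passed, and with the empty-droplet profile 30. Of 14 genes named as risen or fallen, 6 stayed past the threshold without each library in turn.

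In malignant-like cells, interferon genes were higher after whole-body radiation, and cholesterol synthesis and cell-cycle genes were lower. Of the interferon list 17 of 36 members rose and none fell (30 and 0 adjusted over the list alone), including Irf7, a regulator of interferon production (2.01 ± 0.29), Ifit3 (1.77 ± 0.29), Ifit3b (1.80 ± 0.25), Ifit1 (1.76 ± 0.20) and Ifi44 (1.79 ± 0.28), and outside the list Isg20 (2.12 ± 0.32) and Ifi204 (1.68 ± 0.23). Isg15 (1.23 ± 0.32) had an adjusted p of 0.07. Of the cholesterol list 17 of 18 fell (18 adjusted over the list alone), with Insig1 (-1.06 ± 0.08), Fdps (-0.83 ± 0.09), Hmgcs1 (-0.82 ± 0.10) and Cyp51 (-0.77 ± 0.08). Of the G2/M list 12 of 28 fell (26 adjusted over the list alone), such as Birc5 (-0.54 ± 0.11) and Mki67 (-0.41 ± 0.09), and of the G1/S list 5 of 27 (22 adjusted over the list alone), such as Rrm2 (-0.53 ± 0.09). Of the p53 list 6 of 30 rose (14 up and 2 down adjusted over the list alone), among them Cdkn1a (0.83 ± 0.11), Ak1 (0.71 ± 0.07) and Trp53inp1 (0.60 ± 0.08). Mdm2 (0.28 ± 0.07), Ccng1 (0.25 ± 0.08) and Phlda3 (-0.04 ± 0.10) did not pass. The chemokine gene Ccl5 (2.26 ± 0.22), the adhesion gene Mcam (1.16 ± 0.10), Axl (0.97 ± 0.18), Fn1 (1.02 ± 0.19), the heme oxygenase gene Hmox1 (0.78 ± 0.09) and Angpt2 (0.48 ± 0.09) rose. The transferrin receptor gene Tfrc (-1.20 ± 0.14), the desaturase gene Scd1 (-1.15 ± 0.18), Id2 (-1.03 ± 0.08), Gcat (-0.87 ± 0.09), Utp14b (-0.79 ± 0.11), Csrp2 (-0.75 ± 0.09) and the melanocyte channel gene Trpm1 (-0.75 ± 0.09) fell. Cd274 (0.66 ± 0.23), H2-K1 (0.42 ± 0.20) and Vegfa (0.18 ± 0.11) did not pass.

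The malignant-like whole-body comparison gave 615 genes up and 395 down. Its clusters shifted in size: cluster 10, led by Ifit3, Iigp1 and Ifit1, held 115 and 179 cells in the non-irradiated control and anti-Ang2 libraries and 542 and 461 in the whole-body ones, and cluster 6, led by Cdc20, Nasp and Rrm2, 1217 and 372 against 356 and 145. Lists of other cells moved too, with 7 of 10 regulatory T cell genes lower and 8 of 25 matrix genes higher and 1 lower when adjusted over the list alone. The count was 0 without the non-irradiated control, 36 without the non-irradiated anti-Ang2, 3018 without the whole-body control and 2508 without the whole-body anti-Ang2 library. With the 10 to 50 UMI profile subtracted 15 genes passed and with the empty-droplet profile 9, although with the latter 900 of the 1010 kept their direction. None of the 30 genes named as risen or fallen stayed past the threshold without each library in turn. Free RNA could make up at most 60% of the Mcam, 42% of the Irf7 and 40% of the Ccl5 UMIs. By markers of macrophage/monocyte-like cells, its limit was 21.2% and 20.97% of the class in the non-irradiated control and anti-Ang2 libraries. In the whole-body ones it was 42.3% and 35.1%, so the limit differed along with radiation. With the 10 to 50 UMI profile the limits showed no common direction. The reported counts were not separated from free RNA.

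Inflammatory, adhesion and hypoxia genes were higher in endothelial-like cells after focused radiation, with 130 genes up and 18 down. Of the inflammatory macrophage list 7 of 10 tested members rose (8 and 0 adjusted over the list alone), of the adhesion list 7 of 13 (9 and 0 adjusted over the list alone) and of the senescence-secretory list 6 of 12 (6 and 0 adjusted over the list alone), and none of the 3 lists had a member down. Examples were Cxcl9 (1.62 ± 0.16), Cxcl1 (1.70 ± 0.17) and Vcam1 (1.53 ± 0.20). Of the interferon list 14 of 36 rose (26 and 0 adjusted over the list alone), including Gbp2 (1.28 ± 0.17) and Isg15 (0.75 ± 0.17), and of the hypoxia list 8 of 31 (12 and 0 adjusted over the list alone), including the glucose transporter gene Slc2a1 (1.10 ± 0.15) and Egln3 (1.87 ± 0.34). Bmp2 (2.23 ± 0.28), Pgf (1.99 ± 0.16), Ubd (1.97 ± 0.22), Tnfrsf9 (1.69 ± 0.25), Fn1 (1.65 ± 0.28), Cd274 (1.47 ± 0.22) and Cdkn1a (1.35 ± 0.16) rose. The gap junction gene Gja4 (-1.09 ± 0.22), Tril (-1.03 ± 0.20), Mest (-1.03 ± 0.15), Fbln2 (-1.02 ± 0.16), Hist1h2ae (-1.51 ± 0.31) and Birc5 (-0.74 ± 0.17) fell, and free RNA could make up at most 56% and 34% of the Hist1h2ae and Birc5 UMIs. The pigmentation list was lower too, with 2 of 17 members higher and a median of -0.53 (1 down past the threshold, 7 adjusted over the list alone), and free RNA by markers of malignant-like cells was at most 14.7%, 14.1%, 14.2% and 7.55% of the class in the non-irradiated control, non-irradiated anti-Ang2, focused control and focused anti-Ang2 libraries. Of the G2/M list 1 of 28 members fell (3 adjusted over the list alone). Angpt2 (0.60 ± 0.15), Tek (-0.27 ± 0.16), Kdr (-0.08 ± 0.16), Mdm2 (0.18 ± 0.18), H2-K1 (0.54 ± 0.17) and Mki67 (-0.51 ± 0.18) did not pass. The count was 0 without either non-irradiated library, 331 without the whole-body control, 287 without the whole-body anti-Ang2, 293 without the focused control and 77 without the focused anti-Ang2 library. It was 32 by DESeq2's Wald test, 2 with at least 1000 UMIs and 500 genes, 30 and 86 with the 10 to 50 UMI and empty-droplet profiles subtracted, and 285 without the low-count filter, and none of the 20 genes named as risen or fallen stayed past the threshold without each library in turn.

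In macrophage/monocyte-like cells, monocyte, inflammatory, interferon and hypoxia genes were higher after focused radiation, and cell-division genes were lower. Of the monocyte list 6 of 14 members rose (11 and 0 adjusted over the list alone), including Chil3 (2.09 ± 0.29), Vcan (2.21 ± 0.28) and F10 (1.96 ± 0.18). Of the inflammatory list 8 of 21 rose and 1 fell (11 and 1 adjusted over the list alone), including Nos2 (2.53 ± 0.25), Il1a (1.08 ± 0.17) and the prostaglandin synthase gene Ptgs2 (1.02 ± 0.15). Of the interferon list 10 of 36 rose (23 and 0 adjusted over the list alone), with Gbp2 (1.43 ± 0.29) and Gbp4 (1.33 ± 0.26), and of the hypoxia list 11 of 32 (23 and 0 adjusted over the list alone), with Egln3 (1.52 ± 0.23), Slc2a1 (1.17 ± 0.15) and Vegfa (0.83 ± 0.14). The alternative activation list had 5 of 23 up and 3 down (12 and 3 adjusted over the list alone), with Arg1 (2.70 ± 0.16) up and the lipid carrier gene Apoe (-1.45 ± 0.20) down. Of the G2/M list 18 of 28 fell (26 adjusted over the list alone) and of the G1/S list 9 of 27 (20 adjusted over the list alone), with Mki67 (-1.07 ± 0.15), Birc5 (-1.09 ± 0.18), Hmmr (-1.22 ± 0.19) and Tk1 (-1.42 ± 0.17). Cx3cr1, for the fractalkine receptor (-1.47 ± 0.15), Fcrls (-1.61 ± 0.14) and Olfml3 (-1.50 ± 0.14), and Cxcl14 (-1.98 ± 0.20), fell. Among the large rises were those of Ccl17 (4.28 ± 0.45), Inhba (3.75 ± 0.17), the neutrophil chemokine gene Cxcl3 (3.13 ± 0.22), Flrt3 (3.01 ± 0.38), Slc7a2 (2.81 ± 0.22), the leukotriene receptor gene Ltb4r1 (2.48 ± 0.39), Areg (2.44 ± 0.19) and Tarm1 (2.41 ± 0.36). Cd80 (1.79 ± 0.23) and Cd274 (1.31 ± 0.15), both T cell costimulation or checkpoint ligands, Cdkn1a (0.93 ± 0.16) and Mdm2 (0.60 ± 0.15) rose. Isg15 (0.84 ± 0.29), Ccng1 (0.32 ± 0.15) and H2-K1 (0.17 ± 0.15) did not pass.

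Altogether 400 macrophage/monocyte-like genes rose and 183 fell after focused radiation, and 27 of 33 genes named as risen or fallen stayed past the threshold without each library in turn. The mix of clusters shifted in both pairs: cluster 9 held 206 of 1004 and 332 of 1606 cells of the class in the non-irradiated control and anti-Ang2 libraries and 376 of 827 and 843 of 1272 in the focused ones. The matrix list had 4 of 25 members up and 1 down (11 and 1 adjusted over the list alone). The count was 293 without the non-irradiated control, 223 without the non-irradiated anti-Ang2, 1725 without the whole-body control, 1787 without the whole-body anti-Ang2 and 250 without the focused anti-Ang2 library. DESeq2's Wald test gave 241 and the 1000-UMI minimum 25. Subtracting the 10 to 50 UMI profile left none of the 583 genes, and subtracting the empty-droplet profile gave 396.

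In T/NK-like cells 3 genes rose and 2 fell after focused radiation, with 339 at an unadjusted p under 0.05. The granzyme genes Gzmf (4.11 ± 0.31) and Gzmc (2.37 ± 0.39) and the chemokine gene Ccl1 (2.37 ± 0.28) rose, with Gzmf at 0 and 32 UMIs in the non-irradiated control and anti-Ang2 libraries and at 21 and 436 in the focused ones. Izumo1r fell (-1.12 ± 0.20), as did the apolipoprotein E gene Apoe (-1.21 ± 0.23), chosen after its values were seen, of whose UMIs at most 83.1% could be free RNA. Csf2 (1.48 ± 0.31), Themis (0.91 ± 0.20), Isg15 (0.17 ± 0.20) and Mki67 (0.35 ± 0.19) did not pass. Of the effector list 2 of 18 rose (6 and 0 adjusted over the list alone). DESeq2's size factors in the same test gave 3 up and 1 down, and DESeq2's Wald test 1. The count was 46 without the whole-body control, 47 without the whole-body anti-Ang2, 27 without the focused control and 2 without the non-irradiated control library. It was 0 with the 10 to 50 UMI profile subtracted and 2 with the empty-droplet profile. Of the 5 genes, 2 stayed past the threshold without each library in turn.

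In malignant-like cells no gene passed for focused radiation by edgeR's quasi-likelihood test, although 2680 had an unadjusted p under 0.05. By the Wald test of DESeq2, 329 were up and 176 down. When adjusted over the list alone, 23 of 28 G2/M genes and 13 of 18 cholesterol genes were lower, and 18 of 36 interferon and 9 of 32 hypoxia genes higher. Values were 1.44 ± 0.28 for Gbp2, 1.26 ± 0.22 for Ifi204, 1.25 ± 0.20 for H2-T23, 1.22 ± 0.21 for Ccl5, 0.83 ± 0.21 for the hypoxia-induced carbonic anhydrase gene Car9, 0.69 ± 0.14 for Slc2a1 and 0.59 ± 0.11 for Vegfa. They were -0.74 ± 0.08 for Id2, -0.61 ± 0.09 for Trpm1, -0.49 ± 0.08 for Insig1, -0.40 ± 0.11 for Birc5 and -0.36 ± 0.09 for Mki67. Cdkn1a (0.44 ± 0.11), H2-K1 (0.66 ± 0.20), Cd274 (0.84 ± 0.23) and Isg15 (0.81 ± 0.32) did not pass either. Inflammatory macrophage genes were also higher in this class, 8 of 20 when adjusted over the list alone. The count was 1968 without the whole-body control, 2164 without the whole-body anti-Ang2, 128 without the focused control, 46 without the focused anti-Ang2 and 1 without the non-irradiated anti-Ang2 library.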

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

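The tests of a library that stands apart were written before their results were seen, and the other tests in this part were chosen after. Values that went one way in one pair of libraries and the other way in another are given first. With 1 library per condition, none of these differences was tested.

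Focused radiation went with opposite differences in shares of cells under the control antibody and anti-Ang2. The malignant-like share was 4.35 percentage points higher with the control antibody and -11.4 points with anti-Ang2, a gap of 15.7 points. Macrophage/monocyte-like cells differed by -2.65 and 3.54 points, a gap of 6.19, and immune-like cells by -5.01 and 4.39 points, a gap of 9.40.

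In macrophage/monocyte-like cells, the antibody ratio of the MHC class II list had a median log2 of 0.56 in the focused pair and -0.40 in the whole-body pair, a gap of 0.96. The monocyte list stood at 0.54 and -1.23 in these pairs, a gap of 1.77, and the T and NK effector list at 0.53 and -0.57, a gap of 1.10. The oxidative stress list stood at 0.84 in the whole-body pair and -0.26 in the focused pair, a gap of 1.10. For whole-body radiation the monocyte list stood at 0.31 with the control antibody and -0.76 with anti-Ang2, a gap of 1.07. In endothelial-like cells the antibody ratio of the pigmentation list was 0.33 in the whole-body pair and -1.03 in the focused pair, a gap of 1.36. In T/NK-like cells the pigmentation list stood at 0.97 and -0.34 in these pairs, a gap of 1.31, and the checkpoint list at -0.50 and 0.40, a gap of 0.90. The malignant-like markers that set the free-RNA limit moved as the pigmentation list did. From control to anti-Ang2 they went from 1285 to 1558 CPM (whole-body) and 1439 to 647 (focused) in endothelial-like cells. In T/NK-like cells they went from 2090 to 4446 and from 1932 to 1462. The pigmentation gaps were not separated from free RNA. For focused radiation the interferon list of T/NK-like cells was at -0.34 with the control antibody and 0.30 with anti-Ang2, a gap of 0.65.

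Classes whose gene expression was not tested on their own, and clusters without a name, stood above the non-irradiated control library in single libraries. In the focused anti-Ang2 library, fibroblast-like cells made up 8.64% against 1.75%, pericyte-like cells 6.14% against 2.63%, dendritic-like cells 2.69% against 1.46% and NK cell-like cells 1.51% against 0.550%. These are shares of all cells, and malignant-like cells made up less of that library. The 2 libraries also differ in both antibody and radiation. Of 3084 against 2013 named non-malignant cells, 463 against 146 were fibroblast-like and 329 against 220 pericyte-like. Dendritic-like cells were 144 against 122 of these, and NK cell-like cells 81 against 46. The pericyte-like and dendritic-like shares were then not higher. B cell-like cells were 0.302% of the non-irradiated anti-Ang2 library against 0.0239%. Among clusters without a name, cluster 3, led by Gm26870 and AY036118, held 15.1% of the whole-body anti-Ang2 library against 7.56%, and cluster 16, led by Gm26917, 4.64% against 0.407%. Both had few UMIs, with medians of 2977.5 and 2765 per cell, and no marker among their leading genes. The peak of empty droplets lay at 1188.5 UMIs in the whole-body anti-Ang2 library and at 422 in the non-irradiated control. Cluster 12, led by Col2a1 and Hapln1, was higher in every irradiated library. It held 6.47% and 3.82% of the whole-body and focused control libraries against 1.18% of the non-irradiated one. With anti-Ang2 it held 4.52% and 2.26% against 1.41%.

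The first pattern weighed is the lower G2/M expression of endothelial-like cells with anti-Ang2, at a list median of -0.84. Free RNA from malignant-like cells would have to carry it, but the median was -1.04 with the empty-droplet profile subtracted. A non-irradiated control library that stands apart was argued against by the irradiated pairs, which do not use it and whose list medians were at least as far from 0 as -0.87. An effect of the antibody remains a hypothesis, and differences between single tumors stay open because no condition was repeated.

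The second pattern is the higher T cell-like share with anti-Ang2. Fewer malignant-like cells in the denominator are argued against at the UMI minimum used, where T cell-like cells per 100 named non-malignant cells were higher in 3 of 3 pairs, by 6.05 on average. The UMI minimum stays open as a candidate explanation: with at least 1000 UMIs and 500 genes the mean difference was 0.953 and 1 of 3 pairs was higher. The values were then 16.7 and 16.5 without radiation, 6.19 and 4.32 after whole-body radiation, and 7.49 and 12.4 after focused radiation, for control and anti-Ang2, and with 2000 UMIs after scaling to the shallowest library they were 6.71 and 13.8, 4.85 and 4.28, and 4.11 and 15.9, so the whole-body pair was not higher. A biological difference was not separated from it.

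The third pattern is the higher interferon expression of malignant-like cells after whole-body radiation, at a list median of 1.05. With the empty-droplet profile subtracted the median was 1.22, but this cannot decide whether free RNA from other cells carries the pattern. Across the libraries that profile held malignant-like markers at 8567 to 11972 CPM and macrophage/monocyte-like markers at 699 to 1225 CPM. Its subtraction therefore does not isolate RNA from other cells. The ratio between the whole-body and non-irradiated anti-Ang2 libraries, which leaves out the non-irradiated control, had a median of 0.65, which argues against that library alone as the source. Cluster 10, led by Ifit3, Iigp1 and Ifit1, held 115 of 5546 and 179 of 3507 malignant-like cells in the non-irradiated control and anti-Ang2 libraries and 542 of 5091 and 461 of 4168 in the whole-body ones, so more cells in that state and a change in all cells both stay open. Radiation as the cause remains a hypothesis, with free RNA and differences between single tumors open.

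The antibody counts were set against the other splits of the 6 libraries into 3 and 3. There are 10 splits, too few for a share under 0.05. The real split gave 438 genes in endothelial-like cells and the highest other split 0. It gave 57 and 6 in macrophage/monocyte-like cells and 52 and 7 in T/NK-like cells, and in each of these classes 1 split, the real one, reached the count. The 6 and 7 came from splits that part 1 of the radiation pairs. Among other splits that part all 3 pairs, as the real one does, the highest counts were 1 and 0. In malignant-like cells the real split and the highest other split both gave 0, so 10 of 10 reached it.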

How the results depend on the processing

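Minimums of 3000 and of depth-scaled 2000 UMIs, subtraction of the empty-droplet profile, the 25% free-RNA limit, the named non-malignant denominator and counting the low-pigment cluster as malignant-like were chosen after seeing the data, and the other settings before. Values of named genes kept their side of the threshold in 4872 comparisons with an alternative, 835 were no longer past it and 220 newly past it. A change of sign by less than the standard error, in values past it in neither setting, was counted as kept. Another 20, past it in neither setting, changed sign by more than that, and 1 changed sign while past it in at least 1 setting. Counts of genes stayed within 1.5 times in 103 comparisons and moved further in 128. Shares moved less than the spread of the pairs in 105 comparisons, further in 10, and reversed in 14. Where not stated, the cause was not tested. The planned minimum of 500 UMIs and 250 genes was not run, since most barcodes it adds are empty droplets. Libraries were paired within each kind of radiation or antibody, as the terms of the model do. Replicate numbers gave no further pairing, since each condition had 1 library. The whole-body control library held 297164 UMIs of T/NK-like cells, and on simulated counts 64% of 2-fold antibody changes were recovered in that class, against 86% in malignant-like cells. Whether depth accounts for that was not tested.

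Counts below are genes past the threshold, in the order antibody, whole-body and focused radiation where several are given. Leaving out each library in turn moved the counts in malignant-like cells between 0 and 1294, 0 and 3018, and 0 and 2164; in macrophage/monocyte-like cells between 31 and 804, 271 and 1529, and 223 and 1787; in endothelial-like cells between 4 and 664, 0 and 581, and 0 and 331; and in T/NK-like cells between 24 and 212, 14 and 221, and 2 and 47. These refits have 1 residual degree of freedom. The whole-body change of Isg15 in macrophage/monocyte-like cells, 0.15 as reported, lay between -0.70, without the whole-body control library, and 0.83.

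DESeq2's Wald test gave 685, 1527 and 505 genes in malignant-like cells, 280 and 241 for radiation in macrophage/monocyte-like cells, 135, 112 and 32 in endothelial-like cells, and 25, 21 and 1 in T/NK-like cells. No low-count filter gave 378, 1812 and 391 in malignant-like, 379, 1161 and 1019 in macrophage/monocyte-like, 679, 532 and 285 in endothelial-like and 141, 148 and 29 in T/NK-like cells. At least 1000 UMIs and 500 genes, as first fixed, gave 364 for the antibody in malignant-like cells, 1, 236 and 25 in macrophage/monocyte-like cells, 56, 14 and 2 in endothelial-like cells and 18 for the antibody in T/NK-like cells, with malignant-like share differences of -9.84 points (antibody) and 19.3 (whole-body).

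Subtracting the profile of barcodes with 10 to 50 UMIs gave 5 and 15 for the antibody and whole-body radiation in malignant-like cells, 0, 0 and 0 in macrophage/monocyte-like cells, 195 and 30 for the antibody and focused radiation in endothelial-like cells, and 0, 0 and 0 in T/NK-like cells. Subtracting the empty-droplet profile gave 2, 9 and 1 in malignant-like cells, 20 for the antibody in macrophage/monocyte-like cells, 86 for focused radiation in endothelial-like cells, and 30 and 2 for radiation in T/NK-like cells. Fewer genes were tested in malignant-like cells then (14621 against 16007), and the common coefficient of variation rose from 0.0993 to 0.131. Leaving out genes with over 25% free RNA gave 5 and 375 for the antibody and whole-body radiation in malignant-like cells, 35 for the antibody in macrophage/monocyte-like cells, and 30 and 3 for radiation in T/NK-like cells.

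Fitting only the 4 libraries with 1 kind of radiation or none gave 1900 and 1765 for focused radiation in malignant-like and macrophage/monocyte-like cells, 597 and 332 for radiation in endothelial-like cells, and 172 and 44 in T/NK-like cells. Without radiation terms the antibody gave 0 in macrophage/monocyte-like, 19 in endothelial-like and 3 in T/NK-like cells. With no doublets removed, counts were 248 for the antibody in macrophage/monocyte-like cells, 400 for focused radiation in endothelial-like cells, and 25, 43 and 3 in T/NK-like cells. At Leiden resolution 2 they were 15 and 432 for the antibody and whole-body radiation in macrophage/monocyte-like cells. With mitochondrial UMIs under 10% they were 226 and 64 for radiation in endothelial-like cells. At least 3000 UMIs and 1500 genes gave 178 for the antibody in macrophage/monocyte-like cells, and 260 and 2 for the antibody and focused radiation in T/NK-like cells. At 2000 UMIs after scaling to the shallowest library the antibody gave 244 and 448 in these classes.

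Share differences, in percentage points, changed with these settings as follows. For focused radiation, macrophage/monocyte-like cells were at -0.559 with no doublets removed and -0.651 at Leiden resolution 2, while T cell-like and immune-like cells were at 0.925 and 1.76 with at least 3000 UMIs and at 1.24 and 2.57 after scaling. As a share of non-malignant cells, endothelial-like cells differed by -0.0477 and macrophage/monocyte-like cells by 0.552 with the antibody. Whole-body radiation then gave 0.0983 for endothelial-like, -21.3 for macrophage/monocyte-like, -9.30 for T cell-like and -35.0 for immune-like cells, and focused radiation -2.32 for macrophage/monocyte-like and -3.47 for T cell-like cells. As a share of named non-malignant cells, the antibody gave -3.30 for endothelial-like, -8.77 for macrophage/monocyte-like and -4.12 for immune-like cells, whole-body radiation 7.46 for endothelial-like and -8.34 for T cell-like cells, and focused radiation -1.46 for macrophage/monocyte-like and -4.50 for T cell-like cells. With the low-pigment cluster counted as malignant-like, the whole-body difference of that class was 14.4.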

Other observations

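Gene expression in fibroblast-like and pericyte-like cells was not compared in the report, and these levels of fixed vascular genes were chosen after their values were seen. Libraries are given as control and anti-Ang2 within each kind of radiation. Intervals are 95% Poisson intervals of the counts, which hold counting error alone, since each condition had 1 library. No difference was tested, and free RNA was not subtracted.

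In fibroblast-like cells Vegfa stood at 99.3 (82.7 to 118) and 376 (357 to 395) CPM without radiation, 244 (208 to 284) and 408 (391 to 426) after whole-body radiation, and 292 (273 to 312) and 598 (578 to 619) after focused radiation. In pericyte-like cells it stood at 28.3 (20.4 to 38.2) and 33.0 (27.4 to 39.4), 38.0 (22.5 to 60.0) and 80.2 (66.4 to 96.1), and 60.6 (47.9 to 75.7) and 86.9 (76.6 to 98.2) CPM. Angpt2 in pericyte-like cells stood at 57.9 (46.3 to 71.5) and 93.5 (83.9 to 104), 211 (172 to 257) and 152 (133 to 174), and 106 (88.7 to 125) and 147 (133 to 161) CPM. Tek had 20 and 55, 5 and 48, and 35 and 85 UMIs in fibroblast-like cells. That class held 1258278 and 4126875, 664785 and 5407436, and 2979577 and 5551243 UMIs in all, so these counts cannot be compared as they stand. In the pericyte-like cells of each of the 6 libraries Tek had 0 UMIs.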
